A study of Mus musculus with 9 samples.

How the data were processed

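Gene expression was measured by RNA sequencing in the ventricle of newborn CD-1 mice, in 3 libraries each after sham surgery, after apical resection and after apical resection with vagotomy. Per the labels, surgery was performed on postnatal day 1, hearts were collected on postnatal day 2, the lower part of the ventricular apex was frozen, total RNA was extracted with Trizol, and standard Illumina libraries were sequenced on a HiSeq instrument. The labels do not say whether each library came from a separate pup or from separate litters, nor do they give the sex of the pups.

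The submitters named TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff 2.1.1 with the GRCm38 genome. The deposited matrix holds FPKM, expression normalized to transcript length and library size, with a pseudocount of 1 added by the authors, for 14479 genes, each above 1 FPKM in at least 1 library. The authors' deposited Cuffdiff tables give group values in FPKM, a p-value and a q-value for resection against sham and for resection with vagotomy against resection. The pseudocount of 1 was subtracted from the deposited matrix before any other step. No read counts were used, so the sequencing depth of each library and the counting error of each value are unknown, and no test that needs counts was run.

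Gene positions, lengths and GC content came from GENCODE release M21 (GRCm38), in which 14307 of the 14479 gene identifiers were found and 14302 had a position that overlapped the deposited locus. Genes with a mean of at least 1 FPKM over the 9 libraries were tested, which left 13249. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3: all 9 libraries were fitted together with 1 mean per group, the variances were moderated with a mean-variance trend, and each contrast was tested two-sided by limma's moderated test. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05, and limma's moderated F-test was used for any difference among the 3 groups. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so the gene tests rest on the variance shared across genes. The p-values measure only the spread between samples.

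For gene groups, 41 lists of pathways, cell type markers and quality-related genes were written, of which the 37 with at least 5 tested members were compared with all other genes by camera (limma), two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 37 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run beside it. A list score is the mean log2(FPKM + 1) of the list's tested members in a library minus the mean of the sham libraries, with the genes of failed estimates left out. The groups, tests, thresholds, lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. By that rule the text names, for each contrast, the 10 genes with the largest change in each direction among those past the threshold whose 3 libraries all lay on 1 side of the other group's 3 (unnamed gene models and small RNA families left out), up to 4 members of each list with the smallest p, and a set chosen for the question (among them Nrg1, Erbb2, Erbb4, Chrm2, Il6, Il1b, Ccl2, Nppa, Nppb, Ccnb1, Mki67, Myh6 and Postn); genes named outside it are said to be chosen after their values were seen.

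A total of 15 genes carried failed estimates: the authors' tables mark them as having too many fragments to quantify, or they were listed at 0 in all 3 libraries of a group and above 5 FPKM in all the others. They were kept in the tests, and their values are given per library without a fold change. The fold changes of resection against sham and of vagotomy against resection share the resection libraries, so their covariance was compared with that of 100 simulations of unchanged groups with the same sharing. Calls were also compared with those of the authors' Cuffdiff tables. The procedure was also run on simulated data of the same size, with genes drawn independently of each other and changes set in genes with a log2 mean above 2. It recovered 10.4% to 14.9% of the genes changed by 1 on the log2 scale, 83.6% to 88.1% of those changed by 2 and at least 97.0% of those changed by 3, with 3 to 7 false calls per contrast. A mitosis list lowered by 0.5 was called, with 0 other lists. Without correlation between genes, the simulation cannot show the false calls of genes or lists that such correlation may give.

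That first set of alternatives was pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, upper-quartile and quantile scaling, a fit to only the 6 libraries compared, moderation without the trend or robust, the replicate number as a block, a stricter q for the authors' calls, and leaving out each library in turn. Those added after seeing the data were leaving out failed estimates, removing the trend with GC content and length from each library (loess, span 0.5), protein-coding genes alone, library weights, and Y-linked expression as a covariate. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and library weights and the estimated correlation used statmod 1.5.0.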

Results

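RNA was sequenced from the apical part of the heart ventricle of newborn CD-1 mice in 9 libraries, 3 each after sham surgery, after apical resection and after apical resection with vagotomy. Apical resection removes the tip of the ventricle, and vagotomy is the transection of the vagus nerve, the main parasympathetic nerve of the heart. Surgery was on postnatal day 1 and collection on postnatal day 2. Expression is in FPKM, so the number of reads behind each value is unknown. The median over the 14479 listed genes was 7.52 to 8.29 FPKM per library, and pairs of libraries correlated across genes with r from 0.746 to 0.951 (genes are not independent replicates). A mitochondrial tRNA gene, mt-Ta, had the highest value in all 9 libraries. Group values are mean ± SD with n = 3 libraries. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Adjusted p-values are two-sided and come from limma with Benjamini-Hochberg adjustment over the 13249 tested genes. They measure only the spread between samples. Among the 3 groups, 781 genes differed by limma's moderated F-test, against 3441 at an unadjusted p under 0.05. That count fell to 260, 293 and 287 without vagotomy replicates 1, 2 and 3, to 126 without sham replicate 2 and to 203 without sham replicate 3.

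The comparison of resection with sham asked how the apex of the newborn heart responds, on the day after surgery, to the loss of its tip. After resection, transcripts of macrophages, neutrophils, chemokines and matrix-degrading enzymes and their inhibitors were higher than after sham surgery, and those of DNA replication and mitosis were lower (for mitosis the adjusted p was 0.0612 with an estimated correlation). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050 in GRCm38), which encodes the secreted matrix protein osteopontin, rose from 6.26 ± 4.78 to 255 ± 71.5 FPKM (log2 change 5.33, SE 0.53, adjusted p = 0.00326). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), the arginase made by alternatively activated macrophages, rose from 1.28 ± 1.45 to 58.4 ± 22 FPKM (log2 change 4.80, SE 0.53, adjusted p = 0.00484). Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), the chemokine that draws monocytes into tissue, rose from 12.9 ± 6.2 to 163 ± 51.9 FPKM (log2 change 3.61, SE 0.38, adjusted p = 0.00373). S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), a subunit of the neutrophil protein calprotectin, rose from 20.8 ± 9.77 to 165 ± 45.5 FPKM (log2 change 2.99, SE 0.39, adjusted p = 0.0112).

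Among 28 tested monocyte and macrophage markers, 9 rose and 0 fell (19 rose when adjusted over the list alone), with a median log2 change of 1.26 (camera adjusted p = 6.8e-35, and 0.011 with an estimated correlation). Gpnmb, a glycoprotein of phagocytes, rose from 0.243 ± 0.106 to 6.79 ± 1.92 FPKM, adjusted p = 0.00373, and the lysozyme gene Lyz2 from 27.2 ± 11.6 to 159 ± 46.9 FPKM, adjusted p = 0.0165. Cd14, the co-receptor for bacterial lipopolysaccharide, rose from 1.92 ± 0.136 to 29.3 ± 19.97 FPKM, adjusted p = 0.0408, and Lgals3, which encodes galectin-3, from 1.03 ± 0.768 to 19.2 ± 15.9 FPKM, adjusted p = 0.0355. The list score was 1.56 ± 0.23 in the resection libraries against 0.00 ± 0.19 in sham, and the vagotomy libraries lay at 1.68 ± 0.16. Of 18 tested cytokines and chemokines, 6 rose (14 when adjusted over the list alone), with a median of 2.02 (adjusted p = 1.4e-31, and 0.0125 with an estimated correlation). Besides Ccl2 these included the monocyte chemokine Ccl7 (5.45 ± 2.76 to 58.3 ± 28.1 FPKM, adjusted p = 0.00828) and Ccl6 (7.0 ± 7.79 to 96.8 ± 72 FPKM, adjusted p = 0.0408). The macrophage inflammatory proteins Ccl3 (0.102 ± 0.0389 to 3.27 ± 0.648 FPKM, adjusted p = 0.0237) and Ccl4 (0.368 ± 0.161 to 6.34 ± 1.8 FPKM, adjusted p = 0.00594) rose as well. Ccl2, Ccl6 and the protease gene Ctss each share a deposited locus with another gene, so their values are less certain. S100a8 was the 1 gene of 12 tested neutrophil markers past the threshold over all genes (11 when adjusted over the list alone), and the list had a median of 1.97 (adjusted p = 6.2e-24, and 0.0159 with an estimated correlation). Csf3r, the receptor for granulocyte colony-stimulating factor, stood at 0.446 ± 0.277 FPKM in sham and 5.43 ± 3.0 FPKM after resection (adjusted p = 0.0547). The acute-phase genes Lcn2 (3.13 ± 0.326 to 25.7 ± 18.4 FPKM, adjusted p = 0.0674), Serpina3n and Hp, which encodes haptoglobin, belong to the IL-6 and STAT3 response. That list rose with a median of 1.18 (adjusted p = 2.9e-16, and 0.0165 with an estimated correlation), with 1 of 22 genes up and 10 when adjusted over the list alone. The NF-kB and TNF response rose as a list (median 0.72, adjusted p = 6.8e-12, and 0.0305 with an estimated correlation). Of its 22 genes 0 passed over all genes and 8 when adjusted over the list alone, among them Nfkbia, the feedback inhibitor of NF-kB (8.36 ± 0.89 to 15 ± 1.99 FPKM, adjusted p = 0.38). C5ar1, the receptor for the complement fragment C5a, rose from 2.68 ± 1.22 to 14.8 ± 1.54 FPKM, adjusted p = 0.00744, and with C3ar1 it was 1 of the 2 complement genes past the threshold when adjusted over the list alone. The complement list had a median of 0.42 (adjusted p = 8.4e-05, but 0.167 with an estimated correlation). Platelet markers rose as a list (median 0.96, adjusted p = 1.0e-08, and 0.0147 with an estimated correlation). Of 7 genes 0 passed over all genes and 4 when adjusted over the list alone, namely Thbs1, Ppbp, Pf4 and Clec1b. Il1b, the gene of interleukin-1 beta, stood at 0.255 ± 0.211 FPKM in sham and 6.58 ± 7.44 FPKM after resection (adjusted p = 0.204). Il6 was not tested, with a mean of 0.470 FPKM over the 9 libraries.

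**Figure D1:**
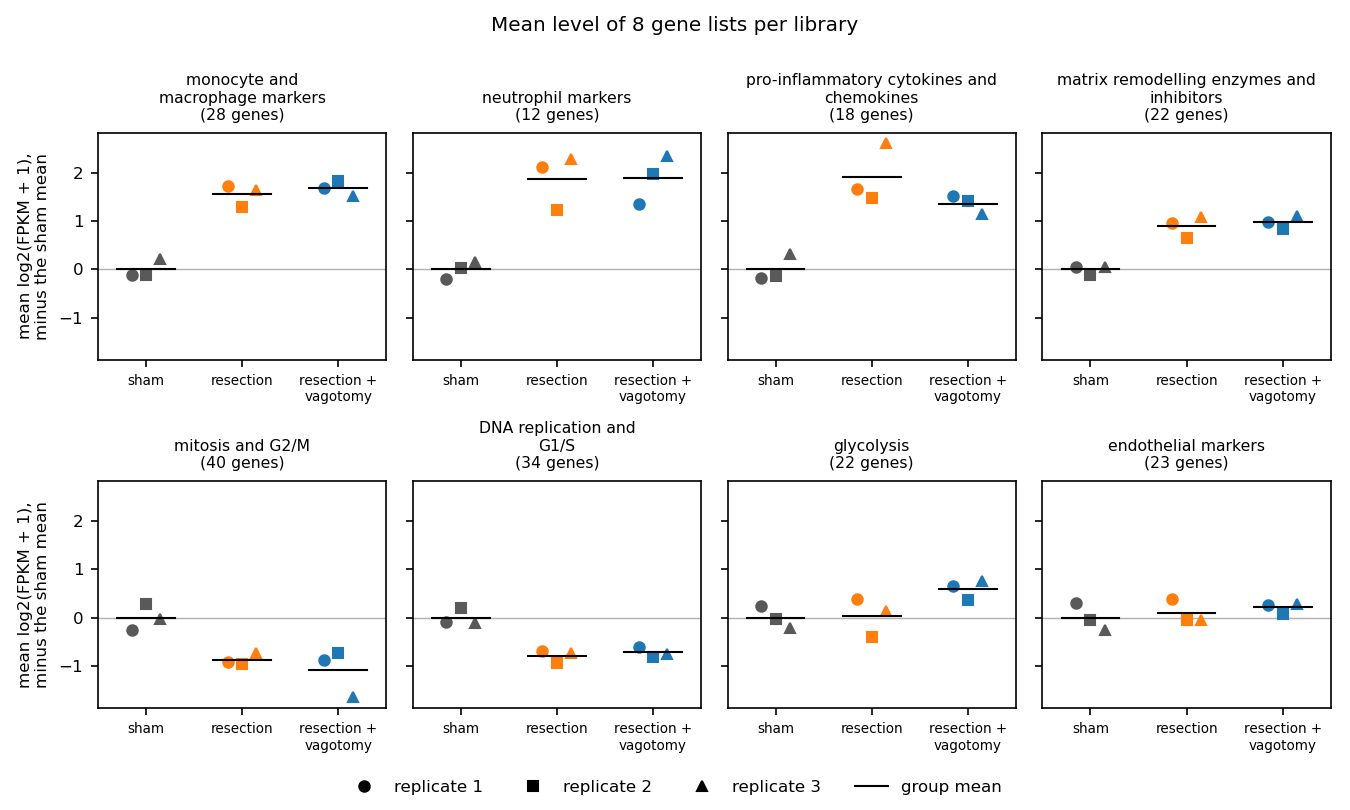
Scores of 8 gene lists in each library (points, with a marker for the replicate number; bars are group means of 3 libraries); the vertical axis is the mean log2(FPKM + 1) of the list's members minus the sham mean. The mitosis scores lie between -0.26 and 0.29 in sham, between -0.96 and -0.73 after resection and between -1.66 and -0.73 after resection with vagotomy.

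The cell cycle lists moved the other way. All 34 tested genes of DNA replication had lower means after resection than in sham, with a median log2 change of -0.79 (adjusted p = 1.6e-27, and 0.0125 with an estimated correlation). By limma 1 gene fell over all genes and 19 when adjusted over the list alone. That gene was Uhrf1 (ENSMUSG00000001228, chromosome 17, 56303321 to 56323486), which recruits the maintenance DNA methyltransferase to newly copied DNA. It went from 22.8 ± 2.59 to 7.5 ± 2.0 FPKM (log2 change -1.51, SE 0.26, adjusted p = 0.0488) and passed the threshold in 8 of 24 alternatives. Rrm2, a subunit of ribonucleotide reductase, stood at 60.01 ± 15.8 FPKM in sham and 18.7 ± 0.834 FPKM after resection (adjusted p = 0.0547). The replicative helicase genes Mcm2 and Mcm5 stood at 25 ± 5.36 and 14.2 ± 2.44 FPKM in sham against 11.2 ± 4.24 and 6.38 ± 0.951 FPKM. All 40 tested mitosis genes had lower means as well, with a median of -0.88 (adjusted p = 1.4e-30, but 0.0612 with an estimated correlation). None of the 40 passed over all genes by limma, and 9 fell when adjusted over the list alone. Top2a, which untangles DNA before division, stood at 71.9 ± 27.2 FPKM in sham and 27.7 ± 6.42 FPKM after resection (adjusted p = 0.196). The proliferation marker Mki67 stood at 10.4 ± 3.09 and 3.64 ± 1.46 FPKM (adjusted p = 0.38), and the mitotic cyclin Ccnb1 at 13.8 ± 4.52 and 7.0 ± 1.28 FPKM (adjusted p = 0.556). Cell cycle inhibitors and p53 targets did not pass as a list (median 0.10, adjusted p = 0.139). Cdkn1a, which encodes the cyclin kinase inhibitor p21, stood at 8.96 ± 1.39 FPKM in sham and 24.6 ± 11.6 FPKM after resection.

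Wound matrix and stress transcripts rose. Matrix remodelling enzymes and inhibitors had a median of 0.56 (adjusted p = 4.2e-15, and 0.0125 with an estimated correlation), with 3 of 22 up over all genes and 8 when adjusted over the list alone. The lysosomal protease gene Ctss rose from 5.63 ± 2.24 to 26.6 ± 4.56 FPKM, adjusted p = 0.011. Timp1, an inhibitor of matrix metalloproteinases, rose from 16 ± 8.16 to 93.9 ± 35 FPKM, adjusted p = 0.0311. The Timp1 locus holds 8 genes, which leaves its value uncertain. Of 24 genes of TGF-beta and BMP signalling 2 rose (2 when adjusted over the list alone), among them Tgfbi, a matrix protein induced by TGF-beta (5.97 ± 0.928 to 21.3 ± 5.09 FPKM, adjusted p = 0.0355). The list had a median of 0.42 (adjusted p = 6.1e-07, and 0.0125 with an estimated correlation). Of 36 matrix genes Spp1 alone rose over all genes, and 5 rose when adjusted over the list alone, namely Spp1, Tnc, Thbs1, Col12a1 and Lox (Lox was chosen after its values were seen). The matrix list rose (median 0.33, adjusted p = 9.8e-06, and 0.0464 with an estimated correlation). The cardiac stress and fetal program rose as a list (median 0.77, adjusted p = 3.9e-06, and 0.0141 with an estimated correlation), with 0 of 17 genes past the threshold and 6 when adjusted over the list alone. Nppb, the gene of the natriuretic peptide BNP, stood at 45.4 ± 21 FPKM in sham and 164 ± 101 FPKM after resection (adjusted p = 0.38). Genes of oxidative phosphorylation were lower as a list (median -0.31, 32 of 34 negative, adjusted p = 1.2e-05, but 0.093 with an estimated correlation), with 0 past the threshold by limma and 0 when adjusted over the list alone. Immediate early genes, among them Fos and Fosl2, were higher as a list (median 0.40, adjusted p = 4.0e-06, but 0.213 with an estimated correlation).

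A further 4 lists passed by less and lost the call with an estimated correlation or without single libraries. Epicardial and mesothelial markers (median 0.16, adjusted p = 0.0179) had 0.234 with an estimated correlation, 0.384 without resection replicate 3 and 0.0652 without sham replicate 1, within 7.6e-05 to 0.384 over all alternatives. The keratin genes Krt18 and Krt8 passed when adjusted over the list alone. Hypoxia response genes (median 0.22, adjusted p = 0.0291) had 0.234 with an estimated correlation, and 0.0954, 0.075, 0.0558 and 0.118 without resection replicates 1 and 3 and sham replicates 1 and 3 (range 0.0116 to 0.234). Erythroid markers (median 0.49, adjusted p = 0.0331) had 0.32 with an estimated correlation, and 0.363, 0.075 and 0.294 without resection replicates 1 and 3 and sham replicate 2 (range 0.00168 to 0.363). The heat shock and unfolded protein response (median 0.20, adjusted p = 0.0339) had 0.239 with an estimated correlation, and 0.171, 0.103, 0.143 and 0.0643 without resection replicates 1 and 2 and sham replicates 1 and 2 (range 0.0153 to 0.239). With the GC and length trend removed the adjusted p was 0.0534 for epicardial, 0.0502 for erythroid and 0.0534 for heat shock genes, with library weights 0.0653 for heat shock and 0.136 for hypoxia genes, and without a filter 0.0563 for epicardial markers.

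Apart from epicardial markers, lists of resident cells and of nerve cells did not pass. The adjusted p was 0.218 for cardiomyocyte sarcomere genes, 0.139 for calcium handling and ion channels, 0.585 for fibroblasts and 0.366 for endothelium. It was 0.103 for smooth muscle and pericytes, 0.098 for atrial and conduction markers, 0.626 for skeletal muscle, 0.384 for neurons and 0.468 for Schwann and glial cells. It was 0.966 for cholinergic and adrenergic receptors, 0.15 for neurotrophin, neuregulin and growth factor signalling and 0.142 for Hippo, Wnt and Notch genes. Metabolic and other lists had 0.607 for fatty acid oxidation, 0.855 for glycolysis, 0.742 for the interferon response, 0.0867 for mitochondrially encoded genes and 0.933 for ribosomal proteins. Of the genes chosen for the question, the muscarinic receptor gene Chrm2 (20.9 ± 6.6 FPKM in sham, 22.1 ± 11.7 FPKM after resection) had an adjusted p above the threshold. So did the neuregulin receptor genes Erbb2 and Erbb4, the natriuretic peptide gene Nppa, the matricellular gene Postn and the myosin gene Myh6. Nrg1 was not analysed here. Leaving out single libraries brought some of these lists past the threshold. Without resection replicate 3 it was sarcomere (0.0374), calcium handling (0.0169), smooth muscle (0.0382) and ribosomal proteins (0.00183, median 0.31). Ribosomal proteins passed in the opposite direction without resection replicate 1 (9.1e-06, median -0.35), smooth muscle without sham replicate 1 (0.0173) and atrial markers without sham replicate 3 (0.0163). Mitochondrially encoded genes passed without resection replicate 1 (0.0276, median 0.10), sham replicate 2 (0.0376, median -0.17) or sham replicate 3 (0.0302, median -0.14). The mitochondrially encoded list holds mt-Co1, a failed estimate listed at 0 in all sham libraries, and its score without that gene was -0.19 ± 0.39 after resection. With a mean of at least 5 FPKM as the filter, neurotrophin, neuregulin and growth factor signalling (0.0293), atrial markers (0.0293), sarcomere (0.0479) and mitochondrially encoded genes (0.0465) passed as well. The highest adjusted p over all alternatives was 0.268 for neurotrophin, neuregulin and growth factor signalling, 0.977 for sarcomere, 0.995 for calcium handling, 0.419 for smooth muscle, 0.32 for atrial markers, 0.532 for mitochondrially encoded genes and 0.991 for ribosomal proteins. The median, the mean and the test differed in sign for 6 lists that did not pass: fibroblast (median -0.07, mean 0.08), fatty acid oxidation (-0.04, 0.12), glycolysis (-0.04, 0.04), mitochondrially encoded genes (-0.26, 2.06, which holds a failed estimate), cholinergic and adrenergic receptors, and ribosomal proteins. A total of 4 lists had too few tested members: T, B and NK lymphocyte markers (1), mast cell and eosinophil markers (3), adipocyte markers (4) and replication-dependent histones (2).

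In all, 39 genes changed between resection and sham, 38 up and 1 down, against 780 at an unadjusted p under 0.05, and 19 of 37 lists passed camera (11 with an estimated correlation, 13 with fry). The groups did not overlap for 10.8% of tested genes, where chance gives 10%. The mitochondrial genes mt-Co1 and mt-Ts1, counted among the 38, were listed at 0 in all 3 sham libraries and marked as failed estimates by the authors (mt-Co1 was 8859, 15284 and 7632 FPKM after resection, and mt-Ts1 263383, 168381 and 24758 FPKM). The count was 18 without sham replicate 1, 11 without sham replicate 2, 21, 66 and 19 without resection replicates 1, 2 and 3, and 24 without vagotomy replicate 2. Of the 39 genes 9 passed in each of the 9 fits that left out a library, among them Spp1, Arg1, Ccl2, Gpnmb, mt-Co1, mt-Ts1, Plek and Gp49a (Plek and Gp49a were chosen after their values were seen). The count was 13 with the 6 compared libraries alone, 417 with library weights, and 89 with the GC and length trend removed. It was 86 with protein-coding genes alone, 74 with robust moderation, and 66 and 23 with pseudocounts of 0.1 and 5.

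**Figure D2:**
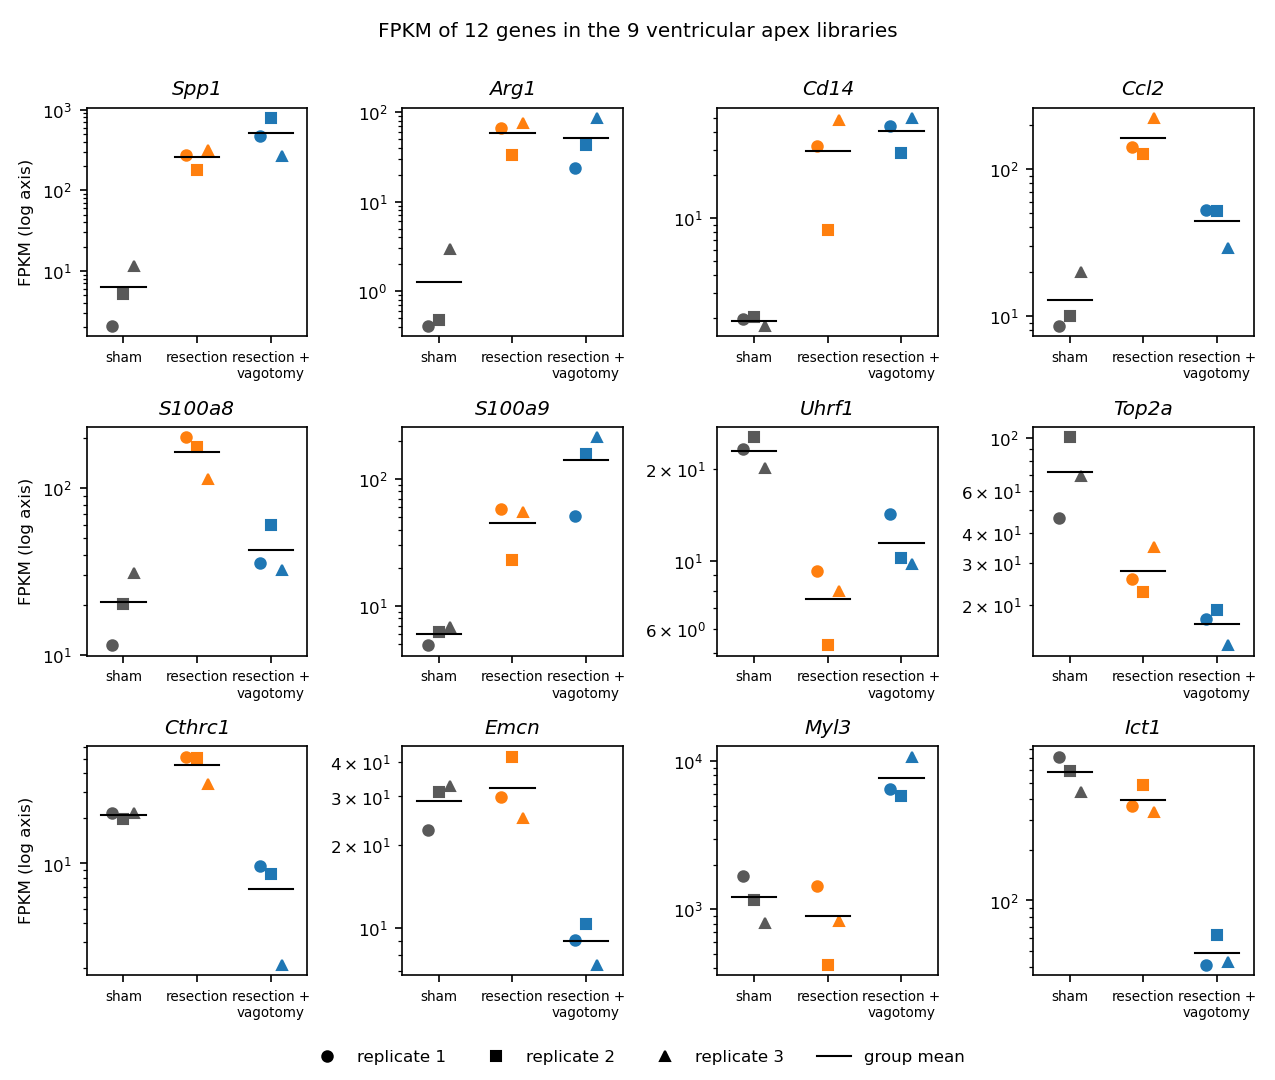
FPKM (logarithmic axis) of 12 genes in each library (points; short lines are arithmetic means of 3 libraries) after sham surgery, resection, and resection with vagotomy. Spp1 rises from a sham mean of 6.26 to 255 after resection, and Ict1 falls from 395 after resection to 49.0 with vagotomy.

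The comparison of vagotomy with resection alone asked what the loss of vagal input changes in the resected heart. With vagotomy, Ccl2 and S100a8, both raised by resection, were lower, while the sarcomere gene Myl3, the acute-phase gene Saa3 and the glycolytic gene Pkm were higher, and the genes called within oxidative phosphorylation, DNA replication, ribosomal proteins and immediate early genes went both ways. Ccl2 fell from 163 ± 51.9 to 44.2 ± 13.3 FPKM (log2 change -1.86, SE 0.38, adjusted p = 0.0337) and S100a8 from 165 ± 45.5 to 42.8 ± 15.3 FPKM (log2 change -1.94, SE 0.39, adjusted p = 0.0344). Their means stayed above the sham means of 12.9 ± 6.2 and 20.8 ± 9.77 FPKM. Myl3 (ENSMUSG00000059741, chromosome 9, 110741861 to 110769798), a ventricular myosin light chain, rose from 898 ± 507 to 7663 ± 2616 FPKM (log2 change 3.21, SE 0.50, adjusted p = 0.0166). Ict1 (ENSMUSG00000018858, chromosome 11, 115403752 to 115412674), a peptidyl-tRNA hydrolase of mitochondrial ribosomes, fell from 395 ± 78.7 to 49 ± 11.7 FPKM (log2 change -2.99, SE 0.30, adjusted p = 0.0014), in a locus of 2 genes. Cthrc1 (ENSMUSG00000054196, chromosome 15, 39076932 to 39087121), a secreted protein of collagen-producing cells, fell from 45.4 ± 9.89 to 6.75 ± 4.06 FPKM (log2 change -2.75, SE 0.42, adjusted p = 0.0166). Emcn (ENSMUSG00000054690, chromosome 3, 137341067 to 137432185), an endothelial sialomucin, fell from 32.3 ± 8.53 to 8.97 ± 1.52 FPKM (log2 change -1.72, SE 0.27, adjusted p = 0.0169). All 3 vagotomy libraries carried Y-linked transcripts above 1 FPKM, against 1 library each of sham and resection.

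Immune transcripts moved in either direction. Cytokines and chemokines had a median of -0.76 and did not pass as a list (adjusted p = 0.103). Of 18 genes 2 fell (2 when adjusted over the list alone), Ccl2 and Cxcl16, a membrane-bound chemokine (5.72 ± 0.817 to 1.61 ± 0.49 FPKM, adjusted p = 0.0263). The list passed without vagotomy replicate 1 (0.0383) and without resection replicate 2 (0.00343), within 1.6e-05 to 0.923 over all alternatives, the lowest with Y-linked expression as a covariate (median -1.33). S100a8 was the 1 of 12 neutrophil markers that passed (1 when adjusted over the list alone). S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), the partner subunit of calprotectin, stood at 45.4 ± 19.5 FPKM after resection and 140.4 ± 82.6 FPKM with vagotomy (adjusted p = 0.119). Both macrophage markers that passed rose: Tyrobp, a signalling adaptor of myeloid cells (19.8 ± 8.55 to 69.4 ± 17.5 FPKM, adjusted p = 0.0244), and Laptm5, a lysosomal membrane protein of blood cells (5.68 ± 0.961 to 16.8 ± 4.2 FPKM, adjusted p = 0.0312). The list of 28 had a median of 0.10 (adjusted p = 0.886; 2 rose when adjusted over the list alone). Bst2, an interferon-induced antiviral protein, fell (8.88 ± 1.17 to 2.71 ± 1.13 FPKM, adjusted p = 0.037) as the 1 of 17 interferon response genes past the threshold (1 when adjusted over the list alone). The ficolin gene Fcna, a lectin of the complement pathway, rose (1.06 ± 1.0 to 10.3 ± 2.6 FPKM, adjusted p = 0.0123), though its locus holds 5 genes. In the IL-6 and STAT3 response 2 of 22 rose, Saa3 (8.21 ± 7.76 to 74.8 ± 53.1 FPKM, adjusted p = 0.037) and the metallothionein gene Mt2 (43.2 ± 24.5 to 189.6 ± 73.5 FPKM, adjusted p = 0.0454), and Mt1 was the 1 added when adjusted over the list alone. The list's median was -0.06 and its mean 0.26, with the test upward (adjusted p = 0.886). Vagotomy replicate 3 had 740 genes listed at 0, against 203 to 311 in the other libraries. All 3 vagotomy libraries stood apart in other measures: 24, 27 and 43 genes with a median above 10 FPKM were listed at 0 in replicates 1 to 3, against 3 to 11 in the other libraries. The top 5 genes held 21.7% to 25.2% of the summed FPKM, against 31.9% to 67.5%, and mt-Ta was 39861 to 74442 FPKM, against 120254 to 1026210 FPKM.

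Among the called genes of muscle and energy lists more rose than fell, as among all 466 calls (261 up and 205 down). None of these lists passed, and fatty acid oxidation had 20 of 30 members negative (median -0.23). Of 25 sarcomere genes 3 rose, Myl3, Tnnc1, the calcium-binding subunit of troponin (825 ± 342 to 6707 ± 5074 FPKM, adjusted p = 0.0294), and the Z-disc gene Actn2 (302 ± 116 to 872 ± 189 FPKM, adjusted p = 0.0442), which was chosen after its values were seen. Adjusted over the list alone, 4 rose. The cardiac actin gene Actc1 and the myosin gene Myh6 were listed at 0 in all 3 vagotomy libraries, and the authors' tables mark both as failed estimates. In the resection libraries Myh6 was listed at 1326, 2255 and 3718 FPKM and Actc1 at 5725, 3600 and 7955 FPKM. With these 2 included, the sarcomere list had a median of 0.46, a mean of -0.31 and an upward test that did not pass (adjusted p = 0.777). Glycolysis came nearest to the threshold (median 0.47, adjusted p = 0.070). The pyruvate kinase gene Pkm (296 ± 146 to 1093 ± 398 FPKM, adjusted p = 0.0405) and Gpi1 (179 ± 27.3 to 407 ± 40.6 FPKM, adjusted p = 0.0425) were the 2 of 22 that rose (7 when adjusted over the list alone). It passed without vagotomy replicate 2 (0.0192) and without resection replicate 1 (0.00689), within 0.00689 to 0.923 over all alternatives. Of 34 genes of oxidative phosphorylation, Sdhc, a membrane anchor of succinate dehydrogenase (156 ± 35.3 to 608 ± 263 FPKM, adjusted p = 0.0306), the cytochrome c gene Cycs (49.3 ± 9.16 to 164 ± 43 FPKM, adjusted p = 0.0337) and Atp5o rose. Ndufs3, a subunit of complex I, fell (190.1 ± 27.6 to 90.9 ± 4.84 FPKM, adjusted p = 0.0456), and the loci of Atp5o and Ndufs3 hold 10 and 4 genes. Adjusted over the list alone, 7 rose and 4 fell, and the list had a median of 0.18 (adjusted p = 0.855). Fabp3, the fatty acid binding protein of heart muscle, rose (683 ± 316 to 2099.7 ± 427 FPKM, adjusted p = 0.0482), and Bnip3, a mitochondrial protein induced by hypoxia, fell (106 ± 24.3 to 38 ± 2.22 FPKM, adjusted p = 0.0336). Among 41 ribosomal protein genes Rplp2 and Rpl23 rose and Rps14 fell (439 ± 182 to 118 ± 9.69 FPKM, adjusted p = 0.0357), with the same counts when adjusted over the list alone. The ribosomal list (median 0.33, adjusted p = 0.855) passed without resection replicate 1 (0.0201; range 0.0201 to 0.976). Tnnc1, Gpi1 and Rplp2 lie in deposited loci of 2 genes and Fabp3 and Rpl23 in loci of 3, so their values are less certain. In the lowest and the highest eighth of protein-coding genes by GC content, the median log2 change was -0.32 and 0.35.

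Cell cycle, matrix and vessel genes gave few calls. Cdc20, an activator of the anaphase-promoting complex (4.16 ± 0.892 to 9.45 ± 1.32 FPKM, adjusted p = 0.0465), and Cdca8, a subunit of the chromosomal passenger complex (2.63 ± 1.44 to 14.7 ± 6.84 FPKM, adjusted p = 0.0337), rose. Of the 40 mitosis genes 0 fell by limma, with the same counts when adjusted over the list alone. The list's median was -0.29 (adjusted p = 0.345), and it passed without vagotomy replicate 1 (0.0383) and without vagotomy replicate 2 (0.0258; range 0.0258 to 0.923). In DNA replication Gins2 rose and Rfc4 fell, each in a locus with many overlapping genes (183 and 7), with 3 up and 3 down when adjusted over the list alone, and the list did not pass (median 0.15, adjusted p = 0.886). Cdc20 and Cdca8 lie in loci of 2 genes. Mki67 stood at 3.64 ± 1.46 FPKM after resection and 4.47 ± 2.41 FPKM with vagotomy (adjusted p = 0.829), and Ccnb1 at 7.0 ± 1.28 and 4.44 ± 1.51 FPKM (adjusted p = 0.273). Cthrc1 and the lysyl oxidase homologue Loxl2 (26.2 ± 13.4 to 3.86 ± 0.639 FPKM, adjusted p = 0.0214, in a locus of 5 genes) were the 2 of 36 matrix genes that fell (4 fell and 1 rose when adjusted over the list alone). Adamts1, a secreted metalloproteinase, rose (9.71 ± 1.53 to 22.2 ± 4.87 FPKM, adjusted p = 0.0378). Emcn was the 1 of 23 endothelial markers past the threshold (1 when adjusted over the list alone), while Pecam1, a junction protein of all endothelium, stood at 37.9 ± 2.22 and 52.4 ± 3.93 FPKM (adjusted p = 0.229). Epicardial markers had a median of -0.49 (adjusted p = 0.103), with the epicardial transcription factor gene Wt1 at 20.9 ± 2.81 and 10.1 ± 3.07 FPKM as the 1 past the threshold when adjusted over the list alone. The epicardial list passed without vagotomy replicate 1 (0.0383), vagotomy replicate 3 (0.0224) or resection replicate 2 (0.00343), within 0.00343 to 0.923. Of 10 cholinergic and adrenergic receptor genes Adra1b, the alpha-1B adrenergic receptor, rose (12 ± 4.08 to 30.2 ± 6.44 FPKM, adjusted p = 0.0491; 2 rose when adjusted over the list alone, with the nicotinic receptor gene Chrnb1). The muscarinic receptor gene Chrm2 stood at 22.1 ± 11.7 and 16.4 ± 4.0 FPKM (adjusted p = 0.673). Erbb2, Erbb4, Il1b, Nppa, Nppb and Postn had adjusted p above the threshold. The immediate early gene Atf3, a stress-induced transcription factor, rose (3.28 ± 1.3 to 15.2 ± 10.9 FPKM, adjusted p = 0.0461) and Dusp6, a phosphatase of the ERK kinases, fell (20.3 ± 3.0 to 9.49 ± 1.91 FPKM, adjusted p = 0.0491).

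Counted over all genes, 466 changed with vagotomy, 261 up and 205 down, against 3212 at an unadjusted p under 0.05. Of them 12 were failed estimates, against 15 among all 13249 tested genes. A further limit is that 105 were not protein coding, while 11939 of the 13249 tested genes were protein coding. By camera 0 of 37 lists passed, against 4 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 with fry. The median, the mean and the test differed in sign for 12 lists, among them sarcomere, IL-6 and STAT3, neutrophil, cardiac stress, immediate early and hypoxia response genes. With library weights the adjusted p was 0.00712 for epicardial markers and 0.0393 for cytokines and chemokines and for ribosomal proteins, with Y-linked expression as a covariate 0.0207 for epicardial markers and 0.013 for glycolysis, and with quantile normalization 0.0378 for glycolysis. The groups did not overlap for 26.2% of tested genes, where chance gives 10%. The count was 133, 208 and 76 without vagotomy replicates 1, 2 and 3, 43 without resection replicate 2, 95 without sham replicate 2 and 141 without sham replicate 3. Of the 466 genes 37 passed in each of the 9 fits that left out a library. They included Ict1, the failed estimates Myh6 and Actc1, and many unnamed gene models and small RNAs. Ccl2, S100a8, Myl3, Saa3, Pkm, Cthrc1 and Emcn were not among them. The count was 24 with Y-linked expression as a covariate, 29 with the 6 compared libraries alone, 887 with library weights and 1351 with the GC and length trend removed.

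**Figure D3:**
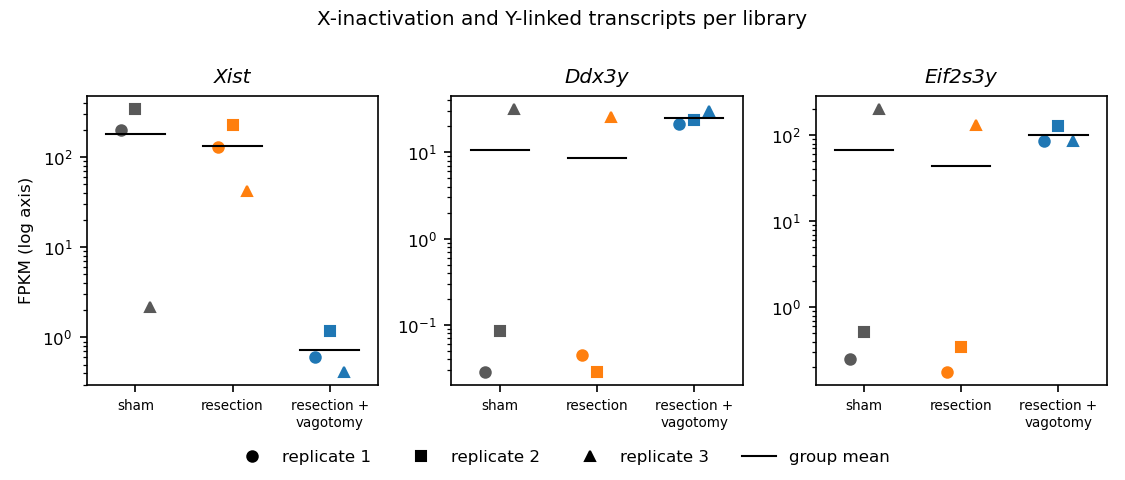
FPKM (logarithmic axis) of Xist, the RNA of the inactive X chromosome, and of the Y-linked genes Ddx3y and Eif2s3y in each library (points) of the 3 groups. Ddx3y is 21.5 to 30.1 FPKM in the vagotomy libraries, and in sham and resection it is above 1 FPKM only in replicate 3 (31.9 and 25.9).

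**Figure D4:**
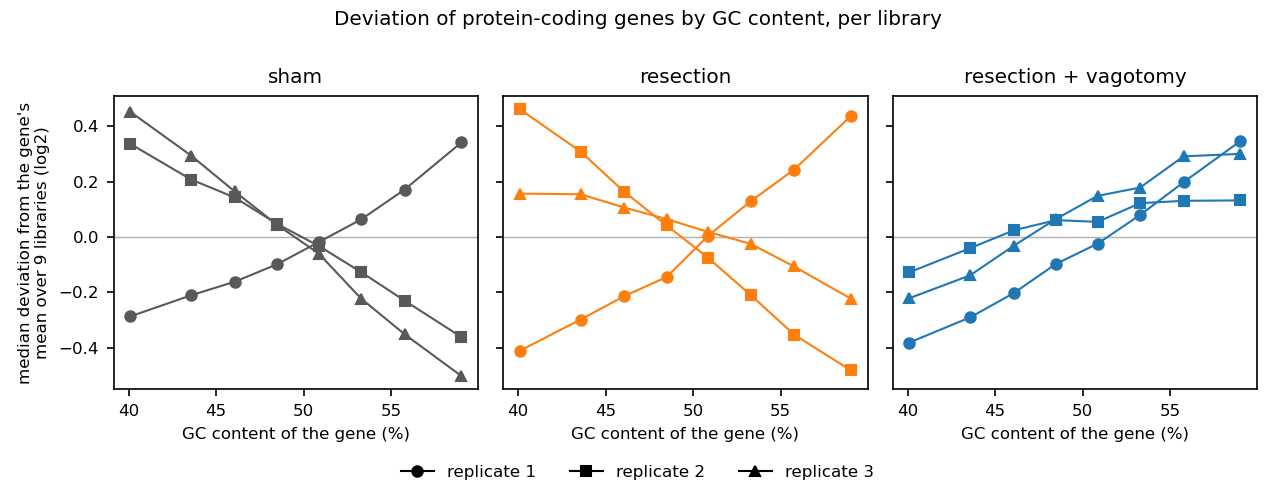
Median deviation (log2) of protein-coding genes from their mean over the 9 libraries, against GC content in 8 bins, with a line for each library and a panel for each group. In the lowest bin, centred on 40.1% GC, the sham libraries lie at -0.29, 0.34 and 0.45 and the vagotomy libraries at -0.38, -0.13 and -0.22.

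Markers of sex and base composition differed between libraries. Xist, in a locus of 7 genes, was 198, 345 and 2.16 FPKM in sham replicates 1 to 3, 131, 228 and 41.7 FPKM in resection and 0.604, 1.17 and 0.418 FPKM in vagotomy, and it fell between resection and vagotomy (adjusted p = 0.0467). Ddx3y, Eif2s3y, Kdm5d and Uty, chosen after their values were seen, were above 1 FPKM in the same 5 libraries (sham replicate 3, resection replicate 3 and all 3 of vagotomy), and resection replicate 3 carried both Xist and these transcripts. Spearman's rho between a gene's deviation and its GC content, across genes within a library, was 0.48, -0.52 and -0.64 in sham, 0.54, -0.60 and -0.33 in resection and 0.45, 0.19 and 0.25 in vagotomy.

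The comparison of vagotomy with sham took resection and vagotomy together, along with the differences in Y-linked expression and library quality between these groups. Most of the inflammatory transcripts that resection raised were also high with vagotomy, though Ccl2 and S100a8 had lower means than after resection alone. Mitosis and replication genes were low. Of the 39 genes called for resection against sham, 37 were called here in the same direction. Both comparisons use the same sham libraries, so this overlap is no independent evidence. The 39 include mt-Co1 and mt-Ts1, failed estimates listed at 0 in all sham libraries. All list calls of vagotomy against sham were lost with an estimated correlation, with adjusted p of 0.195 for macrophage markers, 0.348 for cytokines and chemokines, 0.348 for mitosis and 0.299 for DNA replication. Spp1 rose from 6.26 ± 4.78 to 509 ± 262 FPKM (log2 change 6.23, SE 0.53, adjusted p = 3.1e-04) and S100a9 from 6.01 ± 1.0 to 140.4 ± 82.6 FPKM (log2 change 4.12, SE 0.51, adjusted p = 0.00425). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute-phase protein, rose from 1.47 ± 1.4 to 74.8 ± 53.1 FPKM (log2 change 4.83, SE 0.68, adjusted p = 0.00568). Ctss (ENSMUSG00000038642, chromosome 3, 95526786 to 95556403) rose from 5.63 ± 2.24 to 53.3 ± 0.423 FPKM (log2 change 3.09, SE 0.27, adjusted p = 3.8e-04). Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189) fell from 71.9 ± 27.2 to 16.6 ± 2.83 FPKM (log2 change -1.99, SE 0.32, adjusted p = 0.00929), in a locus of 3 genes.

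Of 28 macrophage markers 15 rose (21 when adjusted over the list alone; median 1.22, adjusted p = 9.2e-12, but 0.195 with an estimated correlation). Among them were Tyrobp (4.83 ± 0.926 to 69.4 ± 17.5 FPKM, adjusted p = 4.3e-04), Gpnmb (0.243 ± 0.106 to 8.4 ± 1.9 FPKM, adjusted p = 5.6e-04) and Cd14 (1.92 ± 0.136 to 40.7 ± 10.9 FPKM, adjusted p = 0.00489). Of 12 neutrophil markers 7 rose (10 when adjusted over the list alone; median 1.71, adjusted p = 7.7e-07, but 0.315 with an estimated correlation). Among them were the gelatinase gene Mmp9 (1.87 ± 0.865 to 15.6 ± 7.94 FPKM, adjusted p = 0.0134) and Retnlg (1.12 ± 0.419 to 26 ± 18.4 FPKM, adjusted p = 0.0114). Of 18 cytokines and chemokines 8 rose (9 when adjusted over the list alone; median 1.25, adjusted p = 2.1e-05, but 0.348 with an estimated correlation). Ccl2 rose from 12.9 ± 6.2 to 44.2 ± 13.3 FPKM, adjusted p = 0.0223, and Il1rn, the antagonist of the interleukin-1 receptor, from 0.266 ± 0.198 to 18.9 ± 2.51 FPKM, adjusted p = 0.00542. The IL-6 and STAT3 response rose (8 of 22 genes, 11 when adjusted over the list alone, adjusted p = 1.5e-05, but 0.315 with an estimated correlation), with Mt2 from 13.4 ± 6.49 to 189.6 ± 73.5 FPKM, adjusted p = 0.00536. The NF-kB and TNF response rose (4 of 22 genes, 8 when adjusted over the list alone, adjusted p = 0.00129, but 0.348 with an estimated correlation), with Nfkbia from 8.36 ± 0.89 to 23.2 ± 4.44 FPKM, adjusted p = 0.0119. Matrix remodelling genes rose (8 of 22, 10 when adjusted over the list alone, median 0.92, adjusted p = 1.5e-05, but 0.212 with an estimated correlation). The cardiac stress program passed (4 of 17 up over all genes and over the list alone, adjusted p = 0.0111, 0.26 with an estimated correlation and 0.0545 without vagotomy replicate 1; range 0.00233 to 0.26). Platelet markers passed (1 of 7, 3 when adjusted over the list alone, adjusted p = 0.0249, 0.348 with an estimated correlation and 0.0696 with Y-linked expression as a covariate; range 0.0113 to 0.348).

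Of 40 mitosis genes 17 fell and 1 rose (28 fell and 1 rose when adjusted over the list alone; median -1.07, adjusted p = 1.8e-12, but 0.348 with an estimated correlation). The kinetochore kinase Bub1 fell from 7.28 ± 2.17 to 0.821 ± 0.786 FPKM, adjusted p = 0.00929, and the spindle motor Kif11 from 17.1 ± 5.51 to 3.2 ± 1.1 FPKM, adjusted p = 0.0101. Ccnb1 fell from 13.8 ± 4.52 to 4.44 ± 1.51 FPKM, adjusted p = 0.0223, while Cdca8 rose. Of 34 replication genes 13 fell and 1, Gins2, rose (16 fell and 1 rose when adjusted over the list alone; median -0.63, adjusted p = 6.6e-07, but 0.299 with an estimated correlation). Cdca8 and Gins2 were chosen after their values were seen. Ccne2, a cyclin of the G1 to S transition, fell from 14 ± 5.78 to 1.34 ± 0.458 FPKM, adjusted p = 0.00599, and Rrm2 from 60.01 ± 15.8 to 15.9 ± 4.26 FPKM, adjusted p = 0.00836. The Ccne2 locus holds 2 genes. Among cell cycle inhibitors and p53 targets 3 of 18 rose (the same number over the list alone), namely Cdkn1a (8.96 ± 1.39 to 53.7 ± 47.7 FPKM, adjusted p = 0.037), Gadd45g and Bax, but the list did not pass (adjusted p = 0.761). The mitosis score of vagotomy replicate 3, the library with 740 genes listed at 0, was -1.66, the lowest of the 9.

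Glycolysis genes rose (3 of 22, 6 when adjusted over the list alone, median 0.71, adjusted p = 0.0111, but 0.725 with an estimated correlation and 0.104 with the GC and length trend removed; range 0.00337 to 0.725). The lactate transporter gene Slc16a3 rose from 3.02 ± 1.15 to 18.9 ± 9.75 FPKM, adjusted p = 0.0185. Of 34 oxidative phosphorylation genes 6 fell, among them Cyc1, a cytochrome of complex III (429 ± 96.9 to 171 ± 13.7 FPKM, adjusted p = 0.0308), and Sdhc rose. Adjusted over the list alone, 6 fell and 4 rose, with the list short of the threshold (adjusted p = 0.425). The median log2 change of the lowest and the highest eighth of genes by GC content was -0.40 and 0.41, and all 3 vagotomy libraries but 1 of the 3 sham libraries carried Y-linked transcripts. Of 36 matrix genes 4 rose (Spp1, Tnc, Thbs1 and Sparc) and 3 fell (Loxl2, Cthrc1 and Col14a1), Sparc and Cthrc1 being chosen after their values were seen. Adjusted over the list alone, 6 rose and 5 fell, and the list did not pass (adjusted p = 0.632). Lists short of the threshold passed without single libraries. Without vagotomy replicate 3 it was complement (0.0343), TGF-beta and BMP signalling (0.0344), mitochondrially encoded genes (0.0343), immediate early genes (0.0367) and smooth muscle markers (0.0473), and without vagotomy replicate 2 immediate early genes (0.0337) and the interferon response (0.040). The others were smooth muscle markers (0.027) and immediate early genes (0.0379) without sham replicate 1, the interferon response without sham replicate 3 (0.0202), and smooth muscle markers without resection replicate 1 (0.0471). Smooth muscle markers also passed with Y-linked expression as a covariate (0.0167), mitochondrially encoded genes with the GC and length trend removed (0.0267) and immediate early genes with library weights (0.0461). The highest adjusted p of these lists over all alternatives ran from 0.461 for smooth muscle markers and 0.647 for TGF-beta and BMP signalling to 0.894 for the interferon response, complement and immediate early genes and 0.93 for mitochondrially encoded genes. The mitochondrially encoded list holds mt-Co1, a failed estimate listed at 0 in all sham libraries.

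Between vagotomy and sham 1334 genes changed, 770 up and 564 down, against 3986 at an unadjusted p under 0.05. Of them 14 were failed estimates, against 15 among all 13249 tested genes, and 179 were not protein coding, while 11939 of the 13249 were. By camera 11 of 37 lists passed (0 with an estimated correlation, 16 with fry), and the median, the mean and the test differed in sign for 7 lists that did not pass, among them sarcomere (median 0.39, mean -0.41). The groups did not overlap for 36.7% of tested genes, where chance gives 10%. The count was 602, 711 and 541 without vagotomy replicates 1, 2 and 3, 83 without sham replicate 2, and 177 without sham replicate 3. It was 59 with Y-linked expression as a covariate, 2300 with the GC and length trend removed and 6389 with library weights.

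Whether vagotomy moved genes against the direction of resection was asked across the 13249 genes. The covariance of the log2 changes for resection against sham and for vagotomy against resection was -0.0542 (Pearson r = -0.13 across genes, which are not independent). The simulated covariance was -0.0825 ± 0.0042 (SD of 100 simulations) for unchanged groups that share the resection libraries, a difference of 0.0282. The simulation drew genes independently of each other and held no tie between libraries of the same replicate number. Its SD therefore leaves out the spread from correlation between genes, and the difference cannot be judged against it. That difference turned negative without resection replicate 1 (-0.0262), resection replicate 3 (-0.0428) or sham replicate 3 (-0.0011), and it was 0.0032 with the GC and length trend removed. Ccl2 and S100a8 were the 2 genes that changed in opposite directions in both comparisons, where 0.608 were expected if the calls were independent, and 0 changed in the same direction. Ccl2 passed in 24 of 24 alternatives for resection and in 17 of 24 for vagotomy, and S100a8 in 21 of 24 and 17 of 24. As 3 resection libraries cannot be divided into independent parts of at least 2, part of these opposite changes can come from the shared libraries alone.

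The authors' Cuffdiff tables called 857 of 14011 genes tested for resection against sham, 586 up and 271 down. They called 2406 of 14083 for vagotomy against resection, 1200 up and 1206 down. Of the 39 genes called here by limma 36 were called there in the same direction (92.3%), where 1.55 were expected if the calls were independent, and these were 4.59% of the 784 authors' calls among the tested genes. For vagotomy it was 345 of 466 (74.0%), where 41.0 were expected, and 14.8% of 2336. With both methods applied to the same libraries, the overlap is no independent evidence.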

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

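The settings with the GC and length trend removed, protein-coding genes alone, library weights, failed estimates removed and Y-linked expression as a covariate were chosen after the data were seen, and the cause of the changes was not tested unless given. No test of read counts such as DESeq2 was run, because counts were not used here. The genes called between resection and sham (39) ranged from 11 to 66 when single libraries were left out. Their number was 89 with the GC and length trend removed, 417 with library weights, 13 with only the 6 samples compared (fewer libraries estimate the variance), 86 with protein-coding genes alone, 66 and 23 with pseudocounts of 0.1 and 5, and 74 with robust moderation. Rises were 97.4% of these calls, against 85.4% with the trend removed and 66.9% with library weights. For vagotomy against resection (466) the range without single libraries was 43 to 596, and the number was 1351 with the trend removed, 887 with library weights, 29 with only the 6 samples compared and 24 with Y-linked expression as a covariate. Rises were 56.0% of the calls, against 37.9% with only the 6 samples compared and 25.0% with the covariate. For vagotomy against sham (1334) the range was 83 to 1701, and the number was 2300 with the trend removed, 6389 with library weights and 59 with the covariate. Among the 3 groups (781) the range was 126 to 1091, and the number was 1847 with the trend removed, 5511 with library weights and 68 with the covariate. Of the gene lists, 11 of 19 passed for resection against sham and 0 of 11 for vagotomy against sham with an estimated correlation in place of the preset one. For vagotomy against resection, where 0 passed, 3 passed with library weights, 1 with quantile normalization and 3 with the covariate, and 0 to 3 without single libraries; for vagotomy against sham the range was 10 to 16. The covariance difference (0.0282) was 0.0032 with the trend removed, 0.0362 both over genes past the F-test and with library weights, 0.0346 with a mean of at least 5 FPKM, 0.0433 with protein-coding genes alone, 0.0382 and 0.017 with pseudocounts of 0.1 and 5, 0.0395 with robust moderation and 0.0337 without failed estimates. Without single libraries it ranged from -0.0428 to 0.0766, and its sign turned without resection replicate 1 (-0.0262), resection replicate 3 (-0.0428) and sham replicate 3 (-0.0011). With a pseudocount of 0.1, 62 genes called for resection were shared with the authors' calls, against 36. Of the single genes and lists past the threshold with all libraries, 0 turned in direction, while the ribosomal protein list of resection against sham, which did not pass, went from a median of 0.02 to -0.35 without resection replicate 1 and to 0.31 without resection replicate 3, and mitochondrially encoded genes from -0.26 to 0.10 without resection replicate 1. Across the alternatives 388 gene results were stronger, 881 weaker and 10186 neither, and 53 list results were stronger, 49 weaker and 2769 neither. Stronger means that a result gained the threshold and weaker that it lost it. Results that passed in neither fit count as neither, even with a turned sign, so these counts do not measure how stable the calls are.

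The labels do not pair the replicate numbers, yet 7 of the 9 libraries correlated best with a library of their own number, a hint from the data alone. In sham, resection and vagotomy, rho with GC content was 0.48, 0.54 and 0.45 for number 1. It was -0.52, -0.60 and 0.19 for number 2 and -0.64, -0.33 and 0.25 for number 3. Whether the match by number follows base composition was not tested. For replicates 1, 2 and 3 the deviations of libraries with the same number correlated with r = 0.498, 0.197 and 0.0129 between sham and resection, 0.186, 0.170 and -0.0193 between sham and vagotomy, and 0.199, 0.141 and 0.117 between resection and vagotomy. The sham and resection libraries titled as replicate 3 carry other numbers in their descriptions. With the replicate number as a block, 1277 genes were called for vagotomy against resection, 2413 for vagotomy against sham and 1632 among the 3 groups, and the covariance difference was 0.0079. Immediate early genes passed as a list for vagotomy against sham with the block (adjusted p = 0.0399, against 0.142).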

Other observations

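Transcripts of vessels, blood and muscle showed changes of single genes between vagotomy and sham where their lists did not pass. The endothelial genes Emcn and Plvap, which forms the diaphragms of fenestrated capillaries, went apart: Emcn fell from 28.8 ± 5.34 to 8.97 ± 1.52 FPKM, adjusted p = 0.0119, and Plvap rose from 5.36 ± 1.5 to 17.3 ± 2.09 FPKM, adjusted p = 0.0378, in a locus of 2 genes. Tagln, an actin-binding protein of smooth muscle and myofibroblasts, rose from 9.33 ± 1.51 to 39.7 ± 7.93 FPKM, adjusted p = 0.00767, in a locus of 6 genes, and Gsn, which severs actin filaments, from 89.7 ± 9.96 to 243 ± 94.9 FPKM, adjusted p = 0.0461. The microfibril gene Mfap5 fell from 61.1 ± 2.43 to 22.6 ± 5.78 FPKM, adjusted p = 0.0166. The alpha-globin gene Hba-a2 rose from 21.8 ± 12 to 101 ± 26.2 FPKM, adjusted p = 0.0313. Casq2, which stores calcium in the sarcoplasmic reticulum of heart muscle, rose from 419 ± 148 to 7027 ± 7780.4 FPKM, adjusted p = 0.0332, with a wide spread between the vagotomy libraries.

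Signalling and stress genes also moved singly. Ddit4, an inhibitor of the growth kinase mTORC1 induced by stress, rose from 10.1 ± 6.4 to 76.2 ± 33.4 FPKM, adjusted p = 0.0129, and Creld2, a chaperone of the endoplasmic reticulum, from 4.99 ± 1.16 to 21.4 ± 9.89 FPKM, adjusted p = 0.0187. Of the phosphatases that switch off MAP kinases, Dusp2 rose from 1.08 ± 0.744 to 4.95 ± 2.06 FPKM, adjusted p = 0.0307 and Dusp1 fell from 38 ± 11.3 to 17 ± 3.48 FPKM, adjusted p = 0.0435. Of the listed cholinergic and adrenergic receptor genes, Adra1b rose from 9.49 ± 2.55 to 30.2 ± 6.44 FPKM, adjusted p = 0.0171 and Chrnb1 from 1.63 ± 0.172 to 6.59 ± 3.18 FPKM, adjusted p = 0.0307. Fgf9, a growth factor of the developing heart, fell from 15.6 ± 2.71 to 7.14 ± 1.44 FPKM, adjusted p = 0.0362, in a locus of 2 genes. In the acyl-CoA dehydrogenases of fatty acid oxidation, Acadl rose from 321 ± 47.6 to 688 ± 161 FPKM, adjusted p = 0.044 and Acadm fell from 716 ± 94.9 to 336 ± 98.8 FPKM, adjusted p = 0.047.

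The tests of dilution by immune cell RNA and of Xist with the Y-linked genes were chosen only after the results were seen, and that of sex in the sham libraries alone after the other test of sex. For the gene counts of 2 groups, 1 of the 10 splits of the 6 libraries reached the real value in each comparison, the real split itself, which is too few splits for a share under 0.05. The real values were 39, 466 and 1334 genes for resection against sham, vagotomy against resection and vagotomy against sham, and the highest of the other splits called 5, 2 and 2. Among the 3 groups, 2 of 100 splits drawn from 280 called at least the real 781, and 1 of them was the real split itself. This argues against chance for the count over all 3 groups, but not for the division of sham from resection. The other split called 2529 and set sham replicate 1 and resection replicates 1 and 3 against sham replicates 2 and 3 and resection replicate 2. In these libraries rho with GC content was 0.48, 0.54 and -0.33 against -0.52, -0.64 and -0.60. The 6 drawn splits that kept the vagotomy libraries together, the real split among them, called 360 to 2529 genes (median 706.5). The others called at most 10, so much of this count came from the vagotomy libraries standing apart from the other 6.

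With the GC and length trend removed 437 of the 466 genes that differed between vagotomy and resection were called in the same direction, which argues against that trend as the whole cause. Y-positive libraries were compared with the others within sham and resection, over the 448 called genes outside X and Y. The median difference, signed by the change, was 0.0752 (95% interval 0.0371 to 0.11, under the bound of 0.798). That value cannot decide on unequal sex of the pups, because genes that follow sex spread within sham and resection and rarely pass. Of the called genes 0 were on Y, though Y-linked genes differed between these libraries. The median rests on 1 Y-positive library in each group, and that of resection also carried Xist. The interval came from resampling genes, so it holds no spread between libraries. A set of 466 genes outside X and Y was chosen instead by their p between vagotomy and the Y-negative resection libraries. That choice took in the 4 Y-linked genes before these were left out. Over this set, the Y-positive sham library differed from the other sham libraries by a median of -0.17 in the direction of the change. The 95% interval, again from resampling genes, was -0.24 to -0.12 (bound 0.892, other sham libraries -0.05 and 0.20). This difference rests on 1 library. Its rho with GC content was -0.64, against 0.45, 0.19 and 0.25 in vagotomy, so the difference cannot be read as an effect of sex alone. With Y-linked expression as a covariate 20 of the 466 called genes passed, as the median SE went from 0.322 to 0.399 and the median signed change from 1.60 to 1.56. Reads divided differently between overlapping genes could not be excluded, with 48.9% of the called genes in shared loci against 45.2% of all tested (upper 95% limit 53.6%, two-sided Fisher's exact p = 0.107), nor could a part played by vagotomy replicate 3, without which 76 genes passed, against 133 and 208 without vagotomy replicates 1 and 2. All 3 vagotomy libraries also stood apart in genes listed at 0 and in the share of the top genes, so a difference in library quality went with the group, and like litter, day of surgery and the added operation itself it was not tested.

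The lower mitosis and DNA replication lists after resection were set against base composition and dilution by RNA of infiltrating immune cells. With the GC and length trend removed their medians were -0.87 and -0.83 and both passed, which argues against that trend. Dilution large enough to cause the list medians of -0.88 and -0.79 would lower resident transcripts alike. The bound for this was set at -0.39 after the results were seen. The lowest median of the resident lists was -0.18 (sarcomere, 95% interval -0.27 to -0.07), with 0.10 for endothelium and -0.07 for fibroblasts, which argues against dilution as the whole cause. That interval came from resampling genes, so it holds no spread between libraries. Oxidative phosphorylation genes, left out of the resident lists, had a median of -0.31 (32 of 34 negative). That fewer cells of the apex were copying DNA on the day after resection is a hypothesis drawn from these libraries and was not tested, since no cells were counted. A loss of the most proliferative tissue with the removed tip, and a change in which cell types divide, stay open and were not tested.

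Xist was lower and Y-linked genes were higher with vagotomy than in the other groups. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were above 1 FPKM in the same libraries, which is consistent with unequal sex of the pups, with more males in that group. Resection replicate 3, with both Xist and Y-linked transcripts, may hold RNA of pups of both sexes, which the labels leave open.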
